A study of Mus musculus with 42 samples.

How the data were processed

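RNA was sequenced from subcutaneous Pan02 tumours of C57BL/6 mice, 42 libraries in 14 groups of 3 mice. Each library came from a separate animal, so the replicates are biological. Replicate numbers follow the order of the sample records and pair nothing across groups. Vehicle tumours were collected at 0 h on days 1, 7 and 14. BXCL701 tumours were collected at 1, 8 and 16 h on day 1 and at 0, 1, 8 and 16 h on days 7 and 14. Vehicle tumours at 1, 8 or 16 h were not analysed here, so comparisons at those hours hold treatment and hour together.

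Per the submitters' processing notes, Trimmomatic 0.36, Bowtie 0.12.9 and the GRCm38 build were used. The quantification tool, the annotation and the scaling step are not given in the sources used here. The deposited gene table is named as counts, but its signal values are not whole numbers. Its lowest peak lay between 0.44 and 0.96 depending on the library, and the next peak lay at 2.42 to 2.57 times that value in every library. Median-of-ratios factors were 0.915 to 1.083. These values were therefore taken as estimated reads that had been scaled per library, not as raw reads. The count-based quasi-likelihood test fixed before the data were examined needs raw reads and was replaced by limma on a log scale. The read depth behind each library is unknown. The lowest peak moved 2.18-fold between libraries, which bounds relative depth only if that peak marks a fixed number of reads. A deposited log2 FPKM table of the same libraries served as an alternative. A further deposited table held the same log2 FPKM values in another gene order (largest difference 0) and was not used. The number of columns belonging to no listed sample was 0.

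Genes with a value of at least 10 in at least 3 libraries were kept, 16613 of 47729. Values were transformed as log2(value + 1), without further scaling, so fold changes are on the log2(value + 1) scale and understate changes of low genes. One linear model with a coefficient for each of the 14 groups was fitted to all 42 libraries (28 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading the deposited files. Moderated statistics used an intensity trend and robust hyperparameters. Adjusted p-values are Benjamini-Hochberg values over the 16613 genes within each of 21 comparisons, with a threshold of 0.05. For the pooled days each harvest hour had equal weight.

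A total of 37 gene lists (pathways, cell-type markers and markers of neighbouring tissue) was fixed at the same time as the test. In 9 comparisons they were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. Counts adjusted over the list alone use the p-values of its members only. The rule for named genes was also fixed beforehand. In each of the 9 comparisons it takes the 10 smallest p-values in each direction among genes past the threshold, leaving out predicted models. Where fewer than 3 passed in a direction, it takes the 3 smallest p-values there, named as not passing. It adds up to 4 members of each list and 13 fixed genes (Dpp4, Fap, Dpp8, Dpp9, Cxcl9, Cxcl10, Cxcr3, Cd274, Ncr1, Cd8a, Il6, Csf3 and Cxcl1). For single harvest times it takes the 3 smallest p-values in each direction.

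Gene positions are those of GENCODE M21 on GRCm38, in which 47310 of the 47729 gene identifiers were found. A transcript-length index was computed for each library as the slope of each gene's deviation from its mean on log2 exon length, over 11491 genes with a mean value of at least 100. A length was available for 99.7% of the tested genes. No pair of libraries was near-identical (highest correlation 0.9813, lowest 0.871).

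The procedure was tested on simulated values with 200 changed genes among 16613, drawn with the means and spread of these libraries. In the simulated day 14 comparison it called 68% of genes raised 2-fold, 86% of genes raised 4-fold, 32% of genes raised 1.5-fold and 46% of genes lowered 2-fold, with 6 false calls. In the simulated comparison of day 14 0 h with vehicle it called 38% of genes raised 2-fold, 78% of those raised 4-fold and 34% of those lowered 2-fold, with 7 false calls. A list raised 2-fold was called, and no other list was. Each gene was drawn independently of the others. The simulation therefore cannot show how many genes or lists are falsely called when genes move together, as those of a list do in these tumours.

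Alternatives fixed beforehand were median-of-ratios factors, no filter, the libraries of each comparison alone, the log2 FPKM table, mean levels of the skeletal muscle, keratinocyte and adipocyte lists as covariates, a 2-fold minimum and leaving out each library. Alternatives chosen after seeing the data were a pseudocount of 5, the transcript-length index as a covariate, and leaving out the 4 libraries whose index lay beyond 0.3 in either direction.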

Results

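Tumours grown from Pan02, a mouse pancreatic adenocarcinoma line, under the skin of C57BL/6 mice were profiled by RNA sequencing during daily oral dosing with BXCL701 at 20 ug per mouse or with vehicle. BXCL701, also known as talabostat, inhibits the dipeptidyl peptidases DPP4, DPP8 and DPP9 and fibroblast activation protein. The 42 tumours formed 14 groups of 3 mice. Over the 16613 genes tested, the first principal component carried 29.2% of the variance and the second 15.4%.

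Markers of neighbouring tissue varied widely between tumours. The mean level of the keratinocyte list had a Pearson correlation of -0.783 with the first principal component. That of the skeletal muscle list had a correlation of -0.585 with the third, which carried 9.5% of the variance. Lists and components are computed from the same values, so these correlations describe their overlap. The mean level of the skeletal muscle list was 11.83 ± 2.05 (SD, n = 3) on the log2 scale at 1 h on day 14 and 6.21 ± 3.82 (SD, n = 3) at 0 h on the same day. The keratinocyte list stood at 7.22 ± 3.02 (SD, n = 3) at 8 h on day 1 and 2.45 ± 0.48 (SD, n = 3) at 8 h on day 14.

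On day 14, BXCL701 tumours carried more transcripts of neutrophil genes than vehicle tumours. Part of the interferon and antigen-presentation genes also rose, but the calls on those lists were lost with an estimated correlation. By fry, which asks only whether a list moves one way on balance, these lists passed. The fry adjusted p was 0.00281 for interferon gamma, 0.00428 for type I interferon, 0.00199 for class I and 0.0121 for class II. Mmp8, the neutrophil collagenase, was 6.46 ± 0.57 (SD, n = 12) against 3.50 ± 0.25 (SD, n = 3), a log2 difference of 2.95 ± 0.42 (SE, adjusted p = 0.00109). Csf3r, the receptor for granulocyte colony-stimulating factor, was higher by 1.34 ± 0.20 (adjusted p = 0.00109). In all, 376 genes rose and 171 fell, and with the transcript-length index as a covariate 1292 rose and 1675 fell. The genes of lowest p that fell were led by Rpl22l1, a ribosomal protein paralog, at -0.91 ± 0.15 (adjusted p = 0.00192), with Wdr89, Sarnp, Gas5, Bcas2, Naca, Nudt2, Mettl10, Sap30 and Tipin at -0.59 to -0.83. All 10 had their highest mean in day 14 vehicle, as for Rpl22l1 at 10.86 ± 0.59 (SD, n = 3), beside 10.20 ± 0.23 and 10.05 ± 0.15 (SD, n = 3 each) in vehicle on days 1 and 7 and 9.95 ± 0.19 (SD, n = 12) under BXCL701 on day 14.

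The remaining genes of lowest p that rose were H2-Q6, H2-Q5, Trpm2, Slfn1, Aoah, Cd84, Ncf1 and Tlr2, with log2 differences of 0.78 to 1.87. H2-Q5, H2-Q6 and H2-Q7 are near-identical class I genes that share reads, so their separate values are uncertain. Of 13 neutrophil genes, 7 rose over all genes and 12 when adjusted over the list alone, among them Ly6g at 2.83 ± 0.55 (adjusted p = 0.00673) and Ngp at 2.93 ± 0.61 (adjusted p = 0.00924). Both genes are low. Ly6g was 3.25 ± 0.91 (SD, n = 12) under BXCL701 and 0.43 ± 0.38 (SD, n = 3) in vehicle. Ngp was 3.87 ± 1.17 (SD, n = 12) and 0.94 ± 1.09 (SD, n = 3). Camera called the neutrophil list higher (adjusted p = 1.16e-13), and that call held with an estimated correlation (adjusted p = 0.0105). Of 22 interferon gamma response genes, 12 rose (18 adjusted over the list alone), with Nlrc5, a transactivator of class I genes, at 1.47 ± 0.27 (adjusted p = 0.00383) and Gbp4 at 2.12 ± 0.46 (adjusted p = 0.0121). The camera call on this list (adjusted p = 2.86e-17) was lost with an estimated correlation (adjusted p = 0.0944). Of 10 class I presentation genes 6 rose, including H2-K1 and B2m, and all 10 did when adjusted over the list alone (camera adjusted p = 1.21e-10, adjusted p = 0.0913 with an estimated correlation). Of 22 type I interferon genes 6 rose (17 adjusted over the list alone), among them Oas2, Oasl2, Mx1 and Ifih1, and the call (adjusted p = 1.87e-11) became adjusted p = 0.106 with an estimated correlation. Of 8 class II genes 3 rose (7 adjusted over the list alone), with Ciita, their master regulator, at 2.08 ± 0.43 (adjusted p = 0.00948), and the list's adjusted p of 4.14e-07 became an adjusted p = 0.16 with an estimated correlation.

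Some genes of cytotoxic lymphocytes rose against day 14 vehicle, but the calls on the cytotoxic effector, T cell and NK cell lists were lost with an estimated correlation. By fry these lists passed (adjusted p = 0.00199, adjusted p = 0.0167 and adjusted p = 0.0167 in that order). Cd8a was 7.46 ± 0.49 (SD, n = 12) under BXCL701 on day 14, and 7.91 ± 0.78, 7.23 ± 0.62 and 6.02 ± 0.47 (SD, n = 3 each) in vehicle on days 1, 7 and 14. Against vehicle of days 1 and 7 the T cell list of these BXCL701 tumours had a median difference of -0.12. Against day 14 vehicle Cd8a, a subunit of the CD8 co-receptor, rose by 1.44 ± 0.37 (adjusted p = 0.0244), Gzmk by 2.32 ± 0.47 (adjusted p = 0.00839) and Prf1, encoding perforin, by 1.73 ± 0.41 (adjusted p = 0.0168). Of 9 cytotoxic effector genes 3 rose (8 adjusted over the list alone), and of 18 T cell genes 3 rose (10 adjusted over the list alone). Of 10 checkpoint genes 3 rose, Pdcd1, Havcr2 and Tox (7 adjusted over the list alone). With an estimated correlation the calls on these lists gave adjusted p = 0.0923, adjusted p = 0.161 and adjusted p = 0.0913. Cxcl9, a ligand of CXCR3, rose by 1.91 ± 0.48 (adjusted p = 0.0238), while Cxcl10 stood at 0.93 ± 0.38 (adjusted p = 0.171), Cxcr3 at 0.77 ± 0.31 (adjusted p = 0.159), Cd274 at 1.14 ± 0.34 (adjusted p = 0.0589) and Ncr1 at 1.01 ± 0.58 (adjusted p = 0.386), none past the threshold. All 4 genes of the CXCR3 axis list rose when adjusted over the list alone. Camera called that list (adjusted p = 0.000394) and lost the call with an estimated correlation (adjusted p = 0.111), and by fry it passed (adjusted p = 0.00447). Among 12 NK cell genes Prf1, Gzma and Klrc1 rose and Klra4, which encodes the activating receptor Ly49D, fell by 1.60 (SE 0.39, adjusted p = 0.0196). Of 12 macrophage genes 2 rose, Mertk, a receptor for dying cells, by 1.32 ± 0.29 (adjusted p = 0.0111) and Adgre1 by 0.59 ± 0.15 (adjusted p = 0.0244). Fkbp5 and Tsc22d3 rose among 12 glucocorticoid-induced genes, and these 2 lists gave adjusted p = 0.0913 and adjusted p = 0.161 with an estimated correlation. Of the glucocorticoid-induced genes 0 passed in the 0 h comparison of days 7 and 14, where the labelled hours match. Treatment and hour are therefore not separated for Fkbp5 and Tsc22d3. In the inflammasome list Nlrp1a and Casp4 rose and Il18 fell by 0.78 (SE 0.17, adjusted p = 0.0124). All 6 genes of the dipeptidyl peptidase list stood higher (median 0.20), and 0 passed when adjusted over the list alone. Camera did not call that list (adjusted p = 0.0924), and by fry it passed (adjusted p = 0.0167). The drug targets did not pass: Dpp4 was 0.94 ± 0.37 (adjusted p = 0.154), Dpp8 0.34 ± 0.24 (adjusted p = 0.514), Dpp9 0.17 ± 0.12 (adjusted p = 0.497) and Fap 0.14 ± 0.59 (adjusted p = 0.949). Il6, Csf3 and Cxcl1 did not pass either (adjusted p = 0.886, adjusted p = 0.834 and adjusted p = 0.837). The proliferation and hypoxia lists were called lower by camera (adjusted p = 0.00046 and adjusted p = 0.000681), and lost the call with an estimated correlation (adjusted p = 0.432 and adjusted p = 0.26). Markers of skin stood lower, with a median of -1.48 over 12 keratinocyte genes, all 12 lower. Adipocyte genes stood higher, all 10 of them (median 1.01), and 13 of 14 skeletal muscle genes lower (median -0.58). No gene of these 3 lists passed, and camera called none of the lists (adjusted p = 0.0989, adjusted p = 0.113 and adjusted p = 0.589). The day 14 count depended on single vehicle tumours: it was 1 gene, Mmp8, without vehicle day 14 replicate 2, 217 without replicate 1 and 2021 without replicate 3. It was also 1 gene when only the day 14 libraries were fitted, and 1018 without the 4 libraries of extreme transcript-length index.

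**Figure D1:**
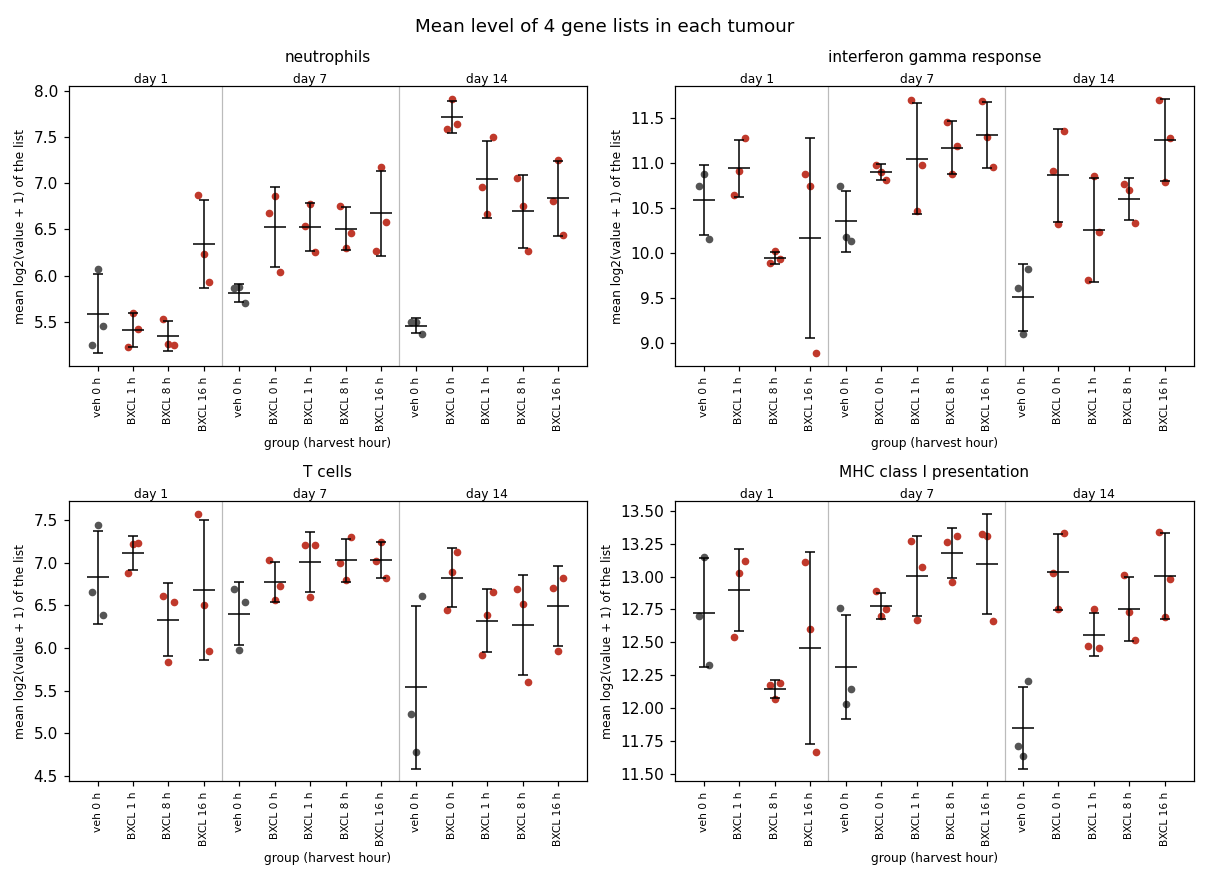
Mean log2(value + 1) of the neutrophil, interferon gamma response, T cell and class I presentation lists in each tumour, by day and harvest hour, with vehicle in grey and BXCL701 in red; black marks are means and SDs of 3 mice. The neutrophil list stood at 7.72 ± 0.17 at 0 h on day 14 under BXCL701 and 5.45 ± 0.08 in vehicle.

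At 0 h, the only hour with vehicle tumours, days 7 and 14 were combined (6 BXCL701 and 6 vehicle tumours). Its day 14 tumours are also part of the day 14 comparison. Neutrophil genes were higher under BXCL701. Mmp8 rose by 2.57 ± 0.38 (adjusted p = 0.00178), Csf3r from 9.67 ± 0.60 to 10.86 ± 0.24 (SD, n = 6 each, adjusted p = 0.00178), Stfa2l1, a stefin gene of neutrophils, by 2.48 ± 0.44 (adjusted p = 0.00966), Ly6g by 2.52 ± 0.49 (adjusted p = 0.0193) and Lcn2, encoding lipocalin 2, by 2.53 ± 0.48 (adjusted p = 0.0128). H2-Q6, Slfn1, Ncf1, Nlrp12, Trpm2 and Sh2d3c also rose, by 0.61 to 1.52. In all, 79 genes rose and 6 fell, namely Klra4, Wdr89, Lgals2, Rpl22l1, Msmo1 and Cdc25c, at -0.55 to -1.58. This one-sided division depended on the model, since 393 rose and 220 fell with the transcript-length index as a covariate.

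Of the 13 neutrophil genes 5 rose (11 adjusted over the list alone), and the list was called with the preset (adjusted p = 9.83e-21) and an estimated correlation (adjusted p = 0.000651). With an estimated correlation the type I interferon, class I, cytotoxic effector and macrophage lists (each adjusted p = 0.0361) and the checkpoint list (adjusted p = 0.0363) also kept their call. The interferon gamma list (3 of 22 genes rose, Nlrc5 among them) had adjusted p = 0.0507 with an estimated correlation, class II adjusted p = 0.0591 and T cells adjusted p = 0.084. By fry these lists passed (adjusted p = 0.00791, adjusted p = 0.00934 and adjusted p = 0.0227 in that order). Cd8a at 1.18 ± 0.33 (adjusted p = 0.0829) and Cxcl9 at 1.46 ± 0.43 (adjusted p = 0.11) did not pass. The proliferation list was called lower (0 of 21 genes fell over all genes and 9 when adjusted over the list alone), with adjusted p = 0.084 with an estimated correlation. Dpp4, Dpp8, Dpp9, Fap, Il6, Csf3, Cxcl1, Cxcl10, Cxcr3, Cd274 and Ncr1 did not pass. The count of 85 genes fell to between 6 and 43 on leaving out any of the 12 libraries except vehicle day 14 replicate 3, without which it was 807. It was 3 without the 4 libraries of extreme transcript-length index and 1 when only the 12 libraries were fitted.

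**Figure D2:**
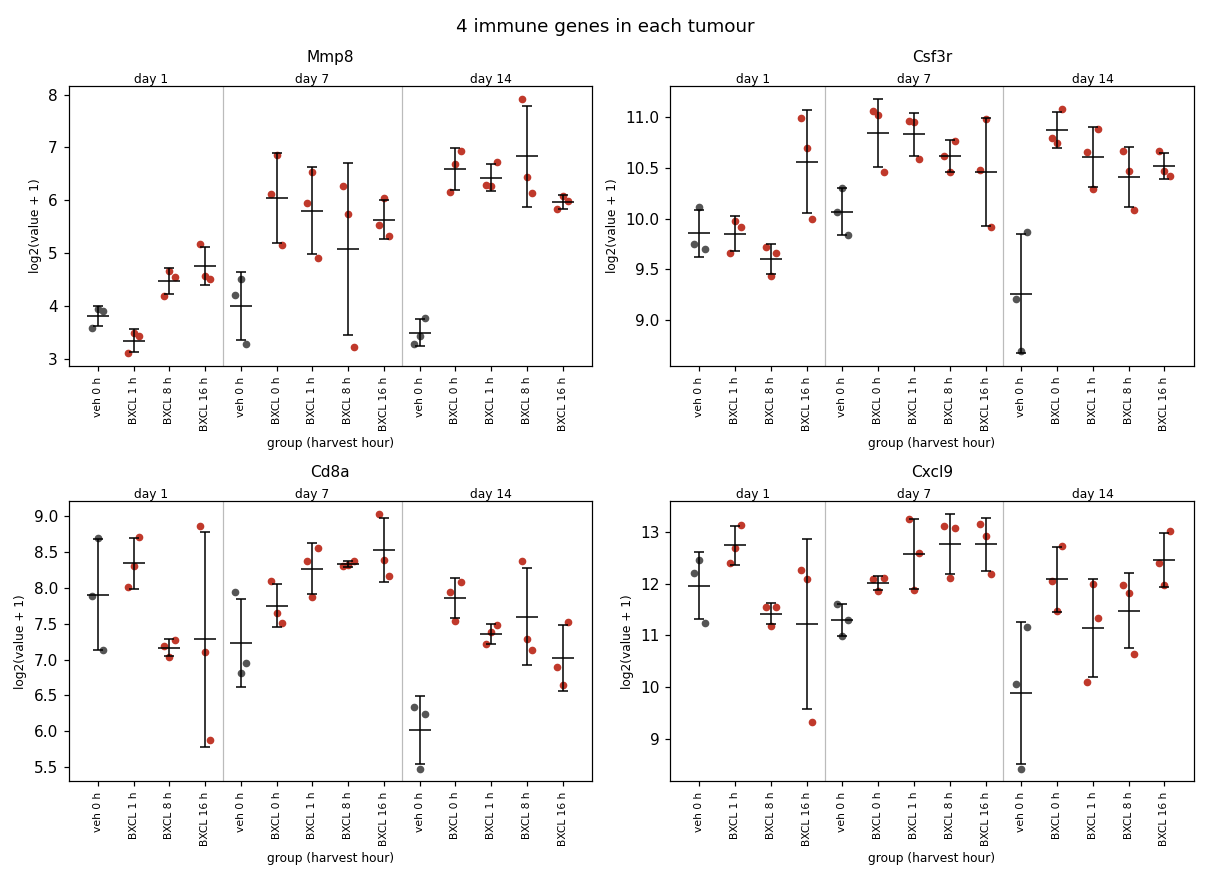
Values of Mmp8, Csf3r, Cd8a and Cxcl9 in each tumour on the log2(value + 1) scale by day and harvest hour, vehicle in grey and BXCL701 in red, with mean and SD of 3 mice in black. Mmp8 averaged 6.46 over the BXCL701 tumours of day 14 and 3.50 in vehicle.

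On day 7, 1 gene passed. Ly86, which encodes the RP105-associated protein MD-1 of B cells and macrophages, was 10.91 ± 0.24 (SD, n = 12) under BXCL701 and 10.09 ± 0.14 (SD, n = 3) in vehicle, a log2 difference of 0.82 ± 0.14 (adjusted p = 0.0215). Hist2h2aa1 at 3.63 ± 0.71 (adjusted p = 0.122), H2-T23 at 0.92 ± 0.21 (adjusted p = 0.287) and, lower, Pif1, Ighv14-3 and Ndc1 had the next smallest p-values and did not pass. An unadjusted p under 0.05 was found for 1640 genes. Mmp8 stood at 1.64 ± 0.42 and Stfa2l1 at 1.97 ± 0.49 (each adjusted p = 0.386), Cxcl9 at 1.23 ± 0.48 (adjusted p = 0.487) and Cd8a at 0.99 ± 0.37 (adjusted p = 0.475).

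Adjusted over the list alone, 9 of 22 interferon gamma genes, 9 of 10 class I genes, 6 of 8 class II genes, 4 of 18 T cell genes, 3 of 9 cytotoxic genes and 3 of 13 neutrophil genes were higher, and 9 of 21 proliferation genes were lower. Of these lists' genes, the proliferation marker Mki67 stood at -0.82 ± 0.26 (adjusted p = 0.462 over all genes). Camera called 15 lists higher and 1 lower, of which 0 held with an estimated correlation (adjusted p = 0.269 for the interferon gamma, class I, class II, cytotoxic, neutrophil and proliferation lists, and adjusted p = 0.444 for T cells). The called lists included red blood cells, all 5 genes higher with a median of 1.38 (adjusted p = 0.00378, adjusted p = 0.409 with an estimated correlation). All 12 keratinocyte genes stood lower, with a median of -1.41, and that list was not called (adjusted p = 0.0552). Neither Dpp4, Dpp8, Dpp9 and Fap nor Il6, Csf3, Cxcl1, Cxcl10, Cxcr3, Cd274 and Ncr1 passed on day 7. The Ly86 call was lost without any single one of the 3 vehicle day 7 replicates. The count was 0 without replicate 1 or 2 and 1, another gene, without replicate 3, and 2 without BXCL701 day 7 8 h replicate 3.

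On day 1 no gene passed with limma, and 437 had an unadjusted p under 0.05. The smallest p-values were those of Sirt4 at 0.84 ± 0.20, Dpysl5 at 1.68 ± 0.46 and Flcn at 0.41 ± 0.12, and of Gzmm at -1.50 ± 0.38, Ubxn8 at -0.40 ± 0.12 and B3gnt4 at -1.78 ± 0.59 (each adjusted p = 0.906). Cxcl1 was 0.97 ± 0.59 and Csf3 1.16 ± 0.77, while Cxcl9 was -0.17 ± 0.50. None of these or of the other fixed genes passed. All 9 mitochondrially encoded genes were higher, 4 of them when adjusted over the list alone (camera adjusted p = 8.46e-07, adjusted p = 0.1 with an estimated correlation). Camera called the glucocorticoid-induced, immediate early and clock lists higher and the cytotoxic, interferon gamma, class I, proliferation and red blood cell lists lower, with adjusted p = 0.1 or more for each with an estimated correlation.

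The harvest hour was examined in BXCL701 tumours of days 7 and 14 against 0 h on the same days. At 8 h, 16 genes rose and 6 fell. Fos, an immediate early transcription factor gene, rose by 2.35 ± 0.27 (adjusted p = 1.23e-05), Dusp1 by 1.70 ± 0.22 (adjusted p = 8.68e-05), Dbp, a clock output gene, by 2.18 ± 0.33 (adjusted p = 0.000949), Tsc22d3, the glucocorticoid-induced leucine zipper gene, by 1.16 ± 0.18 (adjusted p = 0.000968) and Hspa1a, an inducible chaperone gene, by 2.33 ± 0.41 (adjusted p = 0.00537). Arntl, encoding the clock activator BMAL1, fell by 1.24 (SE 0.17, adjusted p = 8.68e-05). Fos stood at 12.36 ± 1.21 (SD, n = 3) at 8 h on day 7 and at 9.37 ± 0.24 (SD, n = 3) at 8 h on day 14, and whether the days differed was not tested.

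Junb, Hist3h2a, Zfp36, Btg2 and Ier2 also rose at 8 h, by 0.75 to 0.96, as did Ciart, Nr1d1, Tef, Hspa8 and Vim, and Ewsr1, Hnrnpdl and Bank1 fell, at -0.52 to -1.32, with the unnamed clone 2410002F23Rik. Of 12 immediate early genes 5 rose (9 adjusted over the list alone), of 16 clock genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), of 8 heat shock genes 2 rose (7 adjusted over the list alone) and of 12 glucocorticoid-induced genes 2 rose (6 adjusted over the list alone). All 4 lists kept their camera call with an estimated correlation, at adjusted p = 0.00142, adjusted p = 0.00114, adjusted p = 0.00294 and adjusted p = 0.00114 in that order. The unfolded protein response and hypoxia lists were called higher (adjusted p = 0.0934 and adjusted p = 0.0961 with an estimated correlation), with Herpud1 rising by 0.50 ± 0.10 (adjusted p = 0.0225). Neutrophil, dendritic cell, type I interferon, endothelial, keratinocyte and adipocyte lists were called lower and red blood cells higher, none with an estimated correlation (adjusted p = 0.258 for neutrophils). Csf3, encoding granulocyte colony-stimulating factor, was 3.94 ± 1.10 (SD, n = 6) at 8 h and 0.99 ± 1.46 (SD, n = 6) at 0 h, a difference of 2.95 ± 0.67 that did not pass (adjusted p = 0.0606). The count was 0 when only these 12 libraries were fitted, 11 without BXCL701 day 14 8 h replicate 1, 14 without BXCL701 day 7 0 h replicate 2 and 72 without BXCL701 day 14 8 h replicate 2.

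**Figure D3:**
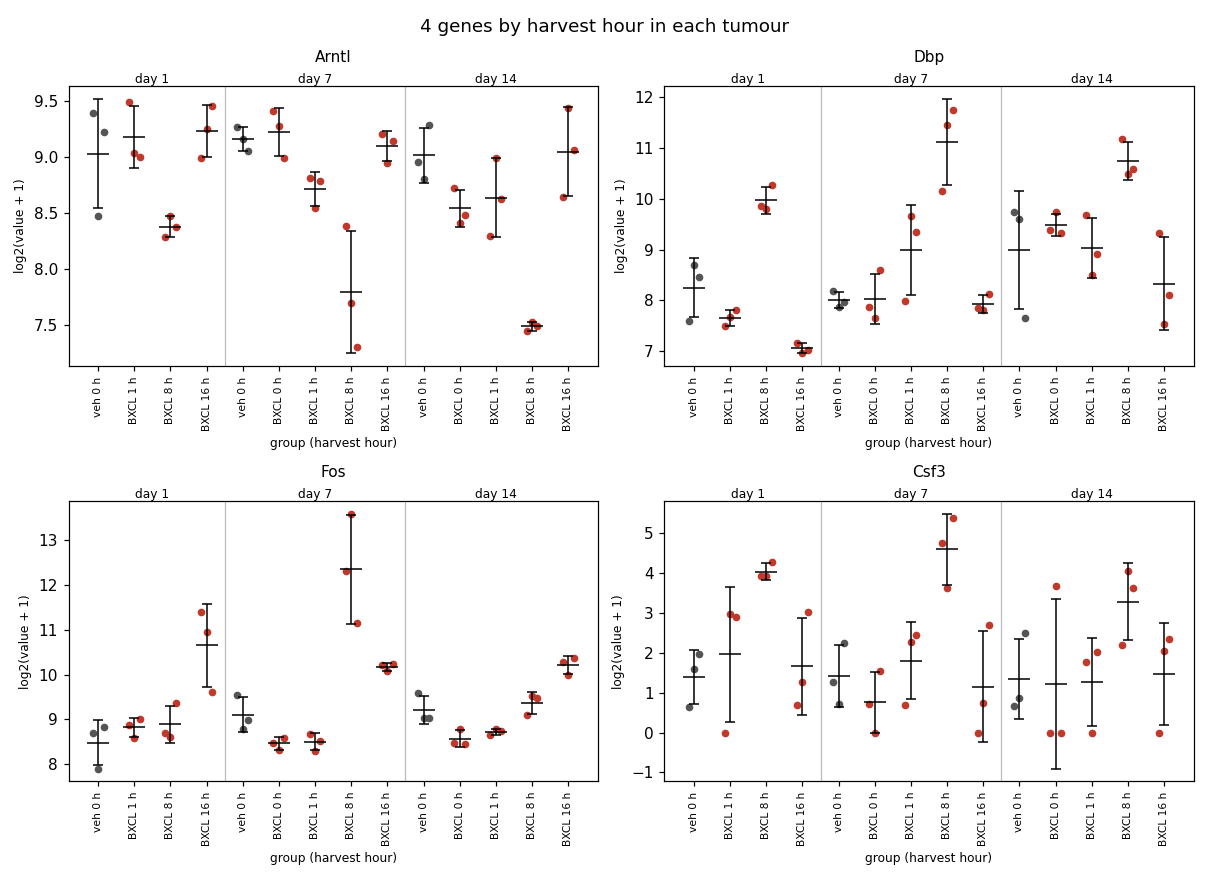
Values of Arntl, Dbp, Fos and Csf3 in each tumour on the log2(value + 1) scale by day and harvest hour, vehicle in grey and BXCL701 in red, with mean and SD of 3 mice in black. Csf3 averaged 3.94 at 8 h and 0.99 at 0 h in the BXCL701 tumours of days 7 and 14.

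At 1 h, 2 genes rose, Tsc22d3 by 1.03 ± 0.18 and Nr4a3, an orphan nuclear receptor gene, by 1.22 ± 0.22 (each adjusted p = 0.0309), and none fell. Per1 at 0.85 ± 0.21 (adjusted p = 0.801), Igkv4-74, Arl4c and Slc22a4 had the next smallest p-values. The glucocorticoid-induced list (1 of 12 rose, 3 adjusted over the list alone) and the heat shock list (0 of 8 rose, 4 adjusted over the list alone) were called higher and kept the call with an estimated correlation (adjusted p = 0.0193 and adjusted p = 0.0253). The skeletal muscle list was also called higher at 1 h, with a median of 2.55, and the keratinocyte list lower, with a median of -1.93 (adjusted p = 0.357 and adjusted p = 0.55 with an estimated correlation). On leaving out 1 library the count was 0 without BXCL701 day 7 0 h replicate 3, day 7 1 h replicate 2, day 14 0 h replicates 1 and 2 and day 14 1 h replicates 1 and 3. It was 1 without day 7 0 h replicate 1, day 7 1 h replicates 1 and 3 or day 14 1 h replicate 2, and 3 without day 14 0 h replicate 3.

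At 16 h, Fos alone rose, by 1.68 ± 0.27 (adjusted p = 0.0103). Egr1 at 0.98 ± 0.21 and Btg2 at 0.77 ± 0.17 (each adjusted p = 0.375) did not pass, nor did Igkv4-74, Patz1 and Usp36 on the lower side. All 12 immediate early genes were higher, 9 of them when adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 0.000257). The other 11 called lists lost it, with adjusted p of 0.401 or more. The Fos call was lost without BXCL701 day 7 0 h replicate 2, day 14 0 h replicate 1 or day 14 16 h replicate 3, and the count was 2 without day 14 0 h replicate 3.

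Single harvest times were set against vehicle of the same day. On day 7 at 8 h, 35 genes rose and 15 fell, with the smallest p-values for Fos at 3.25 ± 0.38 (adjusted p = 1.94e-05), Zfp36 and Ier2, which rose, and Arntl, Bank1 and Hoxa9, which fell. On log2 FPKM that balance turned, with 23 rising and 41 falling. The other day 7 times called 0 genes each, with an unadjusted p under 0.05 for 357, 1214 and 927 genes at 0, 1 and 16 h. On day 14, 116 rose and 14 fell at 0 h, 84 rose and 47 fell at 1 h, 107 rose and 100 fell at 8 h, and 9 rose and 3 fell at 16 h. At 1 h the balance turned with the transcript-length index as a covariate (612 rose and 908 fell). At 8 h it turned with that covariate (664 rose and 872 fell) and without the 4 libraries of extreme index (178 rose and 234 fell). Csf3r, H2-Q6 and Slfn1 rose with the smallest p-values at 0 h, Sla, Rcsd1 and Slfn1 at 1 h, Kctd21, Mmp8 and Tsc22d3 at 8 h, and Trpm2, Gbp8 and Nlrc5 at 16 h. Genes that fell with the smallest p-values were Wdr89, Nudt2 and Sarnp at 0 h, Efna1, Artn and Hilpda at 1 h, Hnrnpd, Arntl and Mphosph6 at 8 h, and Rpl22l1, Fgf15 and Wdr89 at 16 h. On day 1, Egr1 at 1.89 ± 0.30 (adjusted p = 0.0088) and Fos at 2.18 ± 0.38 (adjusted p = 0.0215) rose at 16 h, and no gene passed at 1 or 8 h, where 109 and 2742 genes had an unadjusted p under 0.05. These counts rested on single tumours. Without vehicle day 14 replicate 2 the day 14 counts were 1, 2, 9 and 0 at 0, 1, 8 and 16 h, without replicate 1 they were 0, 43, 103 and 1, and without replicate 3 they were 1253, 1091, 1164 and 990. Leaving out 1 BXCL701 tumour of the same hour gave 4 to 64, 29 to 38, 37 to 91 and 0 to 67. The day 7 8 h count was 10, 16 or 13 without vehicle day 7 replicate 2 or 3 or BXCL701 replicate 3, 608 without vehicle replicate 1 and 2381 without BXCL701 replicate 1. The day 7 16 h count was 1 without vehicle day 7 replicate 3. The day 1 16 h count was 0 without vehicle day 1 replicate 2 or BXCL701 replicate 1 or 2, 1 without vehicle replicate 1 and 3 without BXCL701 replicate 3.

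Vehicle tumours were compared over time. From day 1 to day 14, 9 genes rose and 1 fell. The genes that rose included mt-Nd6 by 1.03 ± 0.18 (adjusted p = 0.0304), mt-Rnr1 by 0.94 ± 0.18 and mt-Nd1 by 0.61 ± 0.12 (each adjusted p = 0.0336), all mitochondrially encoded, and the small nucleolar RNA host genes Snhg1 and Gas5. Ap3m1, Tmem251 and mt-Rnr2 rose as well. The gene that fell, the predicted model Gm15931 at -2.92 ± 0.55 (adjusted p = 0.0336), and a rising one, Gm43857 at 4.29 ± 0.85 (adjusted p = 0.0336), lie outside the naming rule and were added after their values were seen. On the lower side Csrp2bp, Grap2 and Tmem127 did not pass (adjusted p = 0.0627, adjusted p = 0.0717 and adjusted p = 0.0786). Cd8a was 6.02 ± 0.47 (SD, n = 3) on day 14 and 7.91 ± 0.78 (SD, n = 3) on day 1, a difference of -1.89 ± 0.46 that did not pass (adjusted p = 0.123).

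When adjusted over the list alone, 14 of 18 T cell genes, 7 of 9 cytotoxic genes, 14 of 22 interferon gamma genes, 7 of 10 class I genes and 7 of 8 class II genes were lower in vehicle tumours on day 14 than on day 1. Camera called 12 lists lower and 5 higher, and 0 of the 17 held with an estimated correlation (adjusted p = 0.112 for T cells, cytotoxic effectors, class I and class II, and 0.134 for interferon gamma). By fry these lower lists passed, with adjusted p of 0.0172 (cytotoxic effectors) to 0.0324 (interferon gamma). The 5 lists called higher were clock, mitochondrially encoded, hypoxia, immediate early and mast cell genes. Of those, the clock and mitochondrially encoded lists passed by fry (each adjusted p = 0.00978). The count of 10 genes was 0 without any single one of 4 libraries (vehicle day 1 replicates 1 and 2, vehicle day 14 replicates 1 and 2) and 1018 without vehicle day 14 replicate 3, where 400 rose and 618 fell. From day 1 to day 7 no gene passed with limma, and 3051 had an unadjusted p under 0.05. The mitochondrially encoded list was called higher on day 7 and the cytotoxic, class II and skeletal muscle lists lower, with adjusted p = 0.569 or more with an estimated correlation. Olfr613, Klhl15, Spaca6, Rpl22, Tmsb10 and Colgalt1 had the smallest p-values (each adjusted p = 0.263).

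The difference between the BXCL701 effects of day 14 and day 7 was tested as a contrast of its own. No gene passed with limma, and 2592 had an unadjusted p under 0.05, and the larger count on day 14 is therefore not shown to be a difference between the days. Over 1, 8 and 16 h alone 0 genes had a larger and 1 had a smaller effect on day 14, and 3635 had an unadjusted p under 0.05. For the contrast over all hours, the count was 763 in place of 0 without vehicle day 14 replicate 3. It was 1 without BXCL701 day 7 0 h, day 7 1 h, day 14 1 h or day 14 16 h replicate 1.

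Positions on GRCm38 are as follows for the leading genes. Mmp8 lies on chromosome 9 from 7558456 to 7568485, Csf3r on chromosome 4 from 126024550 to 126044440, Cxcl9 on chromosome 5 from 92321347 to 92328079, Ly86 on chromosome 13 from 37345208 to 37419036, Arntl on chromosome 7 from 113207465 to 113314126 and Fos on chromosome 12 from 85473890 to 85477273.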

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

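All tests in this part were chosen or read only after the results they bear on had been seen. The BXCL701 effect over 1, 8 and 16 h was larger on day 14 than on day 1 for 4 lists, by a test of the difference itself (camera with an estimated correlation). The median difference was 1.75 for cytotoxic effectors (adjusted p = 0.0277), 1.16 for neutrophils (adjusted p = 0.0277), 1.49 for interferon gamma response (adjusted p = 0.0409) and 1.05 for class I presentation (adjusted p = 0.0277). Vehicle tumours themselves stood lower on day 14 than on day 1, by medians of -1.57, -0.22, -1.16 and -0.92 in that order. A lower vehicle level may therefore account for most of these differences, except that of neutrophils. A fall with tumour age that BXCL701 tumours did not share would give the same values and was not told apart. Per gene, 0 passed in that difference with limma, and 920 had an unadjusted p under 0.05. The same list test was also run for day 14 against day 7 and for day 7 against day 1. No list passed there with an estimated correlation (adjusted p of 0.991 or more and of 0.776 or more). The list p-values were adjusted within each difference alone.

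The neutrophil, interferon gamma, type I interferon and class I lists together had a median log2 difference of 1.02 on day 14, over all their 66 tested genes. It was 0.87 with the tissue covariates (0.71 to 1.14 on leaving out 1 library), 1.10 with the transcript-length index (0.93 to 1.29) and at least 0.93 without any 1 of the 3 vehicle tumours. All lay above 0.51, a bound chosen after the results, below which most of the median would be lost. Neither these covariates nor leaving out a single vehicle tumour therefore removed most of the median. Interferon gamma levels were low in all 3 vehicle tumours, so leaving out 1 tests little for that list. The count of called genes did rest on 1 tumour, as it fell from 547 to 1 without vehicle day 14 replicate 2. Against the vehicle tumours of days 1 and 7, BXCL701 tumours of day 14 stood 1.07 higher for neutrophils (0.88 to 1.41, of 1.44 on day 14), but 0.25 for interferon gamma response (0.16 to 0.38, of 1.29) and -0.12 for T cells (-0.23 to 0.07, of 0.83). The vehicle tumours of day 14 (replicates 1 to 3) had T cell levels of 5.23, 4.78 and 6.61, so 2 of the 3 were low and replicate 3 lay in the range of day 1 vehicle (6.39 to 7.44), while interferon gamma levels of 9.61, 9.10 and 9.82 lay below all vehicle tumours of days 1 and 7 (10.13 or more). A low level in day 14 vehicle tumours may therefore account for most of the interferon gamma and T cell differences. For neutrophils it may account for little. Vehicle of days 1 and 7 is no control of the same day. A fall with tumour age that BXCL701 tumours did not share would give the same values and was not told apart. On day 7, against vehicle of that day, 22 of 22 interferon gamma genes (median 0.80) and 16 of 18 T cell genes (median 0.55) stood higher. Neither list held its call there with an estimated correlation (adjusted p = 0.269 and adjusted p = 0.444). Whether tumour age or the single animals set the low vehicle level stays open.

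Clock and immediate early genes differed between 8 h and 0 h. At 8 h Arntl stood lower and Dbp higher than in vehicle at 0 h on 3 of 3 days (Arntl at -0.65, -1.37 and -1.53 on days 1, 7 and 14), which the hour of the day could produce without drug. Arntl passed on days 7 and 14 and Dbp on day 7. Fos was also higher than in vehicle on each of those days, by 0.41, 3.25 and 0.15, and passed on day 7 alone. Among BXCL701 tumours of day 14, Fos was 9.09 to 9.53 at 8 h and 8.44 to 8.79 at 0 h. Whether the Fos difference varies between days was not tested. Without vehicle tumours at 8 h, dosing and hour cannot be told apart for the clock or immediate early genes. Tumours labelled 0 h also differed in Dbp. It was 9.73, 9.60 and 7.66 in day 14 vehicle (replicates 1 to 3) and 9.32 to 9.73 in BXCL701 tumours of day 14. On day 7 it was 7.87 to 8.19 in vehicle and 7.65 to 8.59 under BXCL701. The 0 h label is therefore not shown to mark a fixed clock state, and the cause of this spread was not tested. The immediate early list kept a median of at least 0.75 (0.87 as reported) on leaving out 1 library, so no single library carries it, although its mean level was 11.07 ± 0.57 (SD, n = 3) at 8 h on day 7 and 9.63 ± 0.10 (SD, n = 3) at 8 h on day 14.

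The second principal component followed the transcript-length index (Pearson r 0.94, Spearman rho 0.89, permutation p 1e-05 for each, the smallest that 1e+05 resamples can give, and r 0.91 without the 2 libraries farthest from the median). Both are computed from the same values, so these p-values describe their overlap and do not test a length bias. A difference between libraries in RNA integrity or preparation is a candidate source of this component, for which no label gives a measure. The index was 0.004 ± 0.138 (SD, n = 33) in BXCL701 and -0.015 ± 0.189 (SD, n = 9) in vehicle libraries (two-sided permutation p = 0.746, labels exchanged within day), which leaves a treatment effect on it open.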

How the results depend on the processing

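The alternatives with a pseudocount of 5, with the transcript-length index as a covariate and without the 4 libraries of extreme index were chosen after seeing the data, and the others beforehand. Of 143 calls on named genes, 2 were lost with median-of-ratios factors, 4 with a pseudocount of 5, 4 with the index as a covariate, 18 without a filter, 18 on log2 FPKM, 26 with the tissue covariates, 45 without the 4 libraries and 141 with the libraries of each comparison alone, and no called gene changed direction. Leaving out 1 library lost 442 of 1650 such calls. Mmp8 on day 14 kept its call in all 23 fits run for it, between 2.58 and 3.15. A planned count-based alternative (DESeq2) was not run, because the values are not raw reads. No paired analysis was possible because replicate numbers follow the order of the sample records and each tumour is a separate animal. With median-of-ratios factors, the gene count was 0 in day 7, 2 in day 1 8 h alone and 69 in day 14 16 h alone. Without a filter, the gene count was 1 in day 1, 4 in day 7, 35 in the 0 h comparison, 3 in vehicle day 7 against day 1, 1 in day 1 1 h alone, 3 in day 1 8 h alone, 2 in day 7 0 h alone, 22 in day 7 8 h alone, 4 in day 7 16 h alone, 65 in day 14 0 h alone, 105 in day 14 8 h alone and 7 in day 14 16 h alone, and the number of lists called was 7 in vehicle day 7 against day 1. On log2 FPKM, the gene count was 1 in day 1, 0 in day 7, 135 in the 0 h comparison, 12 in 8 h against 0 h, 5 in vehicle day 14 against day 1, 4 in day 1 8 h alone, 4 in day 1 16 h alone and 94 in day 14 16 h alone. With the tissue covariates, the gene count was 4 in day 7, 40 in the 0 h comparison, 1 in 1 h against 0 h, 1 in day 1 8 h alone, 1 in day 1 16 h alone, 77 in day 14 0 h alone and 13 in day 14 1 h alone. At a minimum of 2-fold, the gene count was 0 in day 7, 194 in day 14, 38 in the 0 h comparison, 9 in 8 h against 0 h, 4 in vehicle day 14 against day 1, 75 in day 14 1 h alone and 61 in day 14 8 h alone. With the libraries of each comparison alone, where fewer libraries estimate the spread, the gene count was 0 in day 7, 1 in day 14, 1 in the 0 h comparison, 0 in 1 h against 0 h, 0 in 8 h against 0 h, 0 in vehicle day 14 against day 1, 0 in day 1 16 h alone, 0 in day 7 8 h alone, 0 in day 14 0 h alone, 0 in day 14 1 h alone, 0 in day 14 8 h alone and 0 in day 14 16 h alone, and the number of lists called was 8 in vehicle day 7 against day 1. With the transcript-length index as a covariate, the gene count was 0 in day 7, 2967 in day 14, 613 in the 0 h comparison, 76 in 8 h against 0 h, 301 in vehicle day 14 against day 1, 3 in the difference between days 14 and 7, 4 in day 1 8 h alone, 5 in day 1 16 h alone, 11 in day 7 8 h alone, 1107 in day 14 0 h alone, 1520 in day 14 1 h alone, 1536 in day 14 8 h alone and 372 in day 14 16 h alone. Without the 4 libraries of extreme index, the gene count was 0 in day 7, 1018 in day 14, 3 in the 0 h comparison, 0 in 1 h against 0 h, 12 in 8 h against 0 h, 2 in vehicle day 14 against day 1, 0 in day 1 16 h alone, 6 in day 7 8 h alone, 224 in day 14 1 h alone and 412 in day 14 8 h alone, and the number of lists called was 6 in 16 h against 0 h.

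With an estimated correlation, the number of lists called was 0 in day 1, 0 in day 7, 1 in day 14, 6 in the 0 h comparison, 2 in 1 h against 0 h, 4 in 8 h against 0 h, 1 in 16 h against 0 h, 0 in vehicle day 7 against day 1 and 0 in vehicle day 14 against day 1. By fry, the number of lists called was 0 in day 1, 0 in day 7, 14 in day 14, 14 in the 0 h comparison, 0 in 1 h against 0 h, 6 in 8 h against 0 h, 1 in 16 h against 0 h, 1 in vehicle day 7 against day 1 and 11 in vehicle day 14 against day 1. Leaving out 1 library in turn gave gene counts of 0 to 1018 in vehicle day 14 against day 1, 0 to 3 in day 1 16 h alone, 0 to 2 in day 7, 6 to 807 in the 0 h comparison, 0 to 763 in the difference between days 14 and 7, 10 to 2381 in day 7 8 h alone, 0 to 1 in day 7 16 h alone, 0 to 3 in 1 h against 0 h, 11 to 72 in 8 h against 0 h, 0 to 2 in 16 h against 0 h, 1 to 2021 in day 14, 0 to 1253 in day 14 0 h alone, 2 to 1091 in day 14 1 h alone, 9 to 1164 in day 14 8 h alone and 0 to 990 in day 14 16 h alone. It gave 5 to 14 in day 1, 2 to 7 in vehicle day 7 against day 1, 15 to 20 in vehicle day 14 against day 1, 13 to 22 in day 7, 15 to 19 in the 0 h comparison, 9 to 18 in 1 h against 0 h, 9 to 17 in 8 h against 0 h, 6 to 16 in 16 h against 0 h and 16 to 22 in day 14 lists called. Genes that rose and fell were 634 and 160 on log2 FPKM on day 14 (376 and 171 as reported), 135 and 34 at 1 h on day 14 (84 and 47), 157 and 89 at 8 h on day 14 (107 and 100), 82 and 12 at 16 h on day 14 (9 and 3) and 23 and 41 at 8 h on day 7 (35 and 15). With median-of-ratios factors they were 62 and 7 at 16 h on day 14 and 41 and 28 at 8 h on day 7. With the index as a covariate they were 1292 and 1675 on day 14, 393 and 220 in the 0 h comparison (79 and 6 as reported), 46 and 30 for 8 h against 0 h (16 and 6), 175 and 126 in vehicle day 14 against day 1 (9 and 1), 688 and 419 at 0 h on day 14 (116 and 14), 612 and 908 at 1 h on day 14, 664 and 872 at 8 h on day 14 and 9 and 2 at 8 h on day 7. Total counts of genes or lists that are not named here stayed within 1.5 times the reported count under these alternatives. The cause of each move was not tested, except where fewer libraries or a stricter minimum follow from the alternative itself. The depth behind the scaled values is unknown, so no counting error can be attached to low genes.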

Other observations

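The test of Csf3 and the reading of the sample splits were set only after the results had been seen. Levels of the neutrophil list in BXCL701 tumours of day 1 were 5.41 ± 0.18 at 1 h, 5.34 ± 0.17 at 8 h and 6.34 ± 0.48 at 16 h (SD, n = 3 each), beside 5.59 ± 0.43 (SD, n = 3) in vehicle. On day 7 they were 6.51 to 6.68 at the 4 hours and 5.81 ± 0.10 (SD, n = 3) in vehicle. Mast cell genes stood at 9.48 ± 0.92 (SD, n = 3) in day 14 vehicle and 8.63 ± 0.34 (SD, n = 3) in day 1 vehicle, and hypoxia genes at 10.37 ± 0.12 (SD, n = 3) at 1 h on day 14, beside 11.38 ± 0.14 (SD, n = 3) in vehicle. These levels were not compared by a test of their own, except for the lists of the 9 comparisons.

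Csf3, which encodes the ligand of the receptor gene Csf3r, may peak at the 8 h harvest in BXCL701 tumours. Its level at 8 h was 4.04 ± 0.20 on day 1, 4.60 ± 0.89 on day 7 and 3.29 ± 0.97 on day 14 (SD, n = 3 each), beside 1.82 ± 1.33 (SD, n = 6), 1.23 ± 1.04 (SD, n = 9) and 1.32 ± 1.36 (SD, n = 9) at the other hours. The mean difference of 2.52 gave a two-sided permutation p = 2e-05 with labels exchanged within day. Gene and hour were picked from these same tumours, so this p-value describes the pattern and is no separate evidence for it. On days 1 and 7 each 8 h tumour lay above every other BXCL701 tumour, and on day 14 the lowest at 8 h (2.19) lay below the highest of the others (3.69). The gene is low, several tumours are listed at 0, and no vehicle tumour at 8 h was analysed.

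Other splits of the same libraries were run for each count. Of 100 splits, the real one included, 2 gave as many genes as day 14 (547, highest other 1300), 1 as many as the 0 h comparison (85, highest other 10), 2 as many as 1 h against 0 h (2, highest other 2), 4 as many as 8 h against 0 h (22, highest other 710) and 2 as many as 16 h against 0 h (1, highest other 1). The share was under 0.05 for these. That does not exclude chance, because the shares were read after the results and are not adjusted over the comparisons. On day 14 the splits also exchange vehicle at 0 h with BXCL701 tumours of other hours. For day 7 the share was above 0.05, as 12 splits gave as many genes (1, highest other 7293). For day 1 (0, highest other 18) and for the difference between days 14 and 7 (0, highest other 30) all 100 gave as many, which a count of 0 makes certain, so these splits say nothing about chance. Splits that call many more genes than the real one, as on days 7 and 14 and at 8 h, point to a structure of the samples. Which tumours those splits separate was not tested.

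List counts with the preset correlation were not above other splits. As many lists were called in 64 of 100 splits for day 1 (9, highest other 22), 19 for day 7 (16, highest other 22), 23 for day 14 (17, highest other 23), 20 for the 0 h comparison (16, highest other 27), 35 for 1 h (11, highest other 21), 30 for 8 h (13, highest other 22) and 35 for 16 h (12, highest other 19), so chance could not be excluded for any of these counts.

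Comparisons of 3 with 3 tumours have 10 splits, too few for a share under 0.05, and a count of 0 is matched by all 10 whatever the data. For vehicle day 14 against day 1, 3 of 10 gave as many genes (10, highest other 290) and 2 of 10 as many lists (17, highest other 17), and for vehicle day 7 against day 1 all 10 gave as many genes (0, highest other 1) and 7 as many lists (4, highest other 11). On day 14, 1 of 10 gave as many at 0 h (130, highest other 9) and at 1 h (131, highest other 4), 2 at 8 h (207, highest other 343) and 3 at 16 h (12, highest other 578). The splits with 290 and 578 genes likewise point to a structure of the samples. On day 7, 1 of 10 gave as many at 8 h (50, highest other 0), and all 10 at 0, 1 and 16 h (0, highest other 0 each). On day 1, 1 of 10 gave as many at 16 h (2, highest other 0), and all 10 at 1 h (0, highest other 1) and 8 h (0, highest other 0).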
